A study of Homo sapiens with 4 samples.

How the data were processed

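The series holds 4 arrays of UM-UC-3, an established human bladder cancer cell line. The cells had been stably transfected with GFP alone, the control, or with GFP fused to RhoGDI2, and sorted by fluorescence for the transfected protein. RhoGDI2 is the product of ARHGDIB, a gene described in the series title as a metastasis suppressor. Each group had 2 arrays, replicates A and B. Per the labels, total RNA came from cells in log phase growth, 6 µg of it were turned into biotinylated cRNA, and the array was the Affymetrix HG-U133 Plus 2.0. Per the labels, the replicates are biological, were prepared at different times, and are paired across the groups by preparation. The description field of the GFP-RhoGDI2 samples describes the control transfection, at odds with their title, source, growth protocol and characteristics; the groups were taken from those other fields, which all name the same group for each sample. Whether A and B came from separate transfections is not given in the sources used here. With preparation as a block, p-values rest on how the difference between the lines varies between the 2 preparations, with variances moderated over all probe sets. Differences that arose when each line was made therefore cannot be separated from those due to the introduced gene.

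The deposited values are log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes. The software, its version and which arrays were normalized together are not given in the sources used here. The range and the nearly equal medians of the arrays (4.633 and 4.631 for GFP, 4.624 and 4.647 for GFP-RhoGDI2) showed a log2 scale with arrays already brought to a common level, and no further normalization was applied. Arrays carry no read depth; their number limits the precision. No detection calls were used, so a low value here is a level near the low end of the scale and not an absence.

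Of 54675 probe sets, 62 control probe sets were left out. Of the other 54613, the platform annotation named 1 gene for 41091 and several genes for 1801, and it did not list 11721; the 41091 named 19775 genes. No gene was named from a probe set with several. Probe sets entered the test when their mean over the 4 arrays was at or above the median of that mean, 4.637 on the log2 scale, which left 27307 probe sets and 12123 genes. A gene was represented by its probe set with the highest mean, and log2 fold changes are GFP-RhoGDI2 minus GFP.

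The test was limma 3.58.1 in R 4.3.3, with preparation as a block and moderated variances (lmFit and eBayes), Benjamini-Hochberg adjustment over all probe sets tested, and a call at adjusted p under 0.05. The fit had 1 residual degree of freedom per probe set, to which the moderation added 4.71 with a prior SD of 0.101. The block was in the design because the labels state the pairing; across tested probe sets, the A minus B differences of the groups correlated at r = 0.264. Intervals are at 95%. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 22 lists with at least 3 tested members. Of 628 list entries, 577 were matched on the array. Each list was also tested with an estimated correlation, with ranks and with fry. The test with an estimated correlation rests on the 1 residual degree of freedom of the fit, so it had little power to pass any list. For each list reported, a count adjusted over the list alone is given too; the results of 2 lists are not reported here.

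The groups, the test, the filter, the 25 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names ARHGDIB, 4 genes known from earlier work on RhoGDI2 (VCAN, CCL2, EDN1 and NMU), the 12 called genes with the largest change in each direction and the same sign in both pairs, and the 4 tested members of each list with the largest change. VCAN, CCL2, EDN1 and NMU may have been drawn from these very arrays, so they are not independent evidence. COL12A1, SERPINE2, LTBP2, DDX60 and HERC6 were named outside the rule, after their values were seen, to complete small counts. The alternatives were the fit without the block, each array left out, other filters, an intensity trend or robust moderation, renormalization, a floor, the mean of a gene's probe sets, no probe sets of the shared-transcript classes (identifiers ending in _s_at or _x_at, which can match several transcripts), other thresholds, a fold rule, a plain paired test and other list tests. Added after the data were seen were the list test with an estimated correlation and no block, the removal of genes in regions that shift together, the search for such regions, the share of called genes with shifted neighbours, and the test of zinc finger genes. The search for regions was run a second way after its result was seen: windows with fewer than 50 genes had set the largest value of the shuffled orders, no window passed it, and only full windows were then kept.

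The fit was tested on simulated data with the 27307 probe sets of this comparison, of which 50 were changed at each size. With the block, it recovered 8% of changes of 0.5 on the log2 scale and 100% of changes of 1, 2 and 3, with 15 false calls, and it made 0 calls when nothing was changed. Without the block, it recovered 0% at 0.5, 46% at 1, 98% at 2 and 100% at 3, with 1 false call. Far fewer probe sets were changed there than the 2085 called in the data. The adjusted threshold was therefore stricter in the simulation, and its rates are not those of this comparison. Simulated variances were drawn from the distribution fitted to these arrays, with independent normal noise for each probe set. The false calls therefore do not test that variance model or the effect of correlation between genes. The order of genes along chromosomes came from a RefSeq gene table of assembly GRCh38.p14; the build behind the array's annotation is not given in the sources used here, so no coordinates are printed.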

Results

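Expression was measured on 4 arrays from UM-UC-3 bladder cancer cells that carried either GFP alone or GFP fused to RhoGDI2, with 2 arrays per group. The series asked which genes are regulated by RhoGDI2, the protein encoded by ARHGDIB. Values are log2 RMA expression. Across probe sets, the GFP arrays correlated at r = 0.9958 and the GFP-RhoGDI2 arrays at 0.9964, while arrays of different groups correlated at 0.9912 to 0.9923; these are correlations across probe sets, which are not independent replicates.

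The introduced gene was higher in the GFP-RhoGDI2 line. The ARHGDIB probe set with the highest mean read 6.51 and 6.27 on the GFP arrays A and B and 11.94 and 11.58 on the GFP-RhoGDI2 arrays, a difference of 5.37 (SE 0.095, adjusted p = 8.49e-05) or 41.3-fold. Another ARHGDIB probe set was higher by 0.94 (adjusted p = 0.00794), and the last differed by -0.02 (adjusted p = 0.953). Which of the 3 probe sets lie within the part of the gene carried by the construct was not analysed here.

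Of the genes named from earlier work on RhoGDI2, VCAN, CCL2 and EDN1 changed. VCAN, which encodes the matrix proteoglycan versican, fell from 6.91 ± 0.03 to 3.80 ± 0.22 (SD, n = 2; adjusted p = 2.14e-04); the lower level lies below the filter level of 4.637 and is not shown to be above background, so the size of the fall is uncertain. EDN1, encoding the vasoactive peptide endothelin-1, rose from 6.61 ± 0.22 to 8.48 ± 0.04 (SD, n = 2), 3.67-fold (adjusted p = 0.00102). CCL2, encoding a chemokine that attracts monocytes, rose from 8.44 ± 0.39 to 10.23 ± 0.12 (SD, n = 2), 3.46-fold (adjusted p = 0.00192). NMU, encoding the neuropeptide neuromedin U, was at 4.96 ± 0.07 in GFP and 4.52 ± 0.22 in GFP-RhoGDI2 cells (SD, n = 2), a difference of -0.44 that missed the threshold over all genes (adjusted p = 0.0598). In the limma fit on probe set means it was called (adjusted p = 0.00437). Its difference there was the same, so no further probe set adds to that call. Its GFP-RhoGDI2 level is also below the filter level. Adjusted over the list alone, 2 of the 4 genes were higher and 2 lower, NMU among the latter. These genes may have been chosen on these samples, so neither count is independent evidence.

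**Figure D1:**
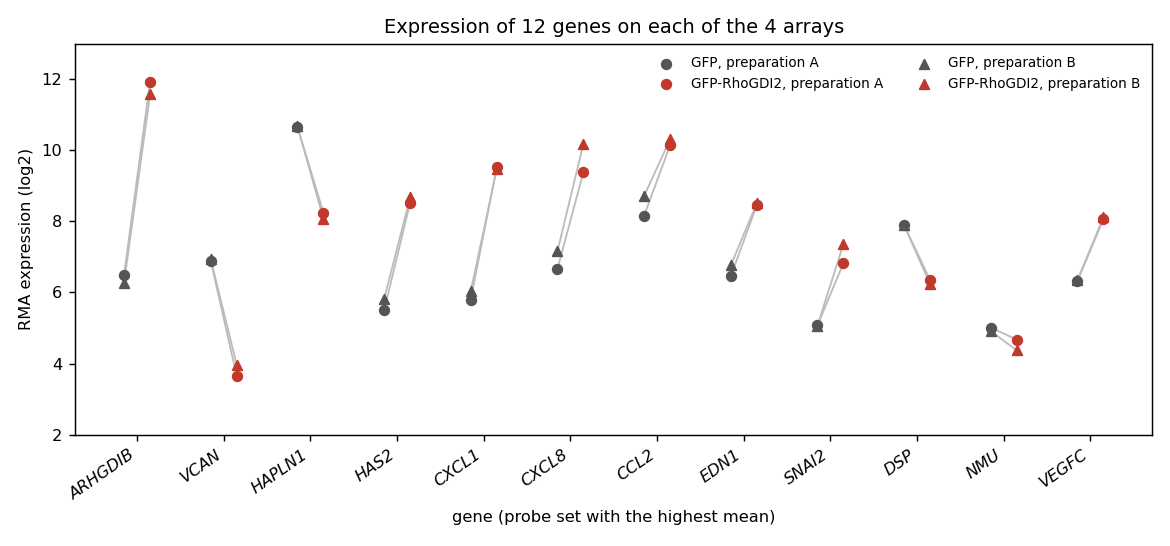
Log2 RMA expression (vertical axis) of 12 genes (horizontal axis) on each of the 4 arrays. Grey symbols are GFP and red symbols GFP-RhoGDI2, circles are preparation A, triangles preparation B, and lines join the arrays of a preparation; ARHGDIB reads 6.51 and 6.27 in GFP against 11.94 and 11.58 in GFP-RhoGDI2, and NMU, which was not called, differs by -0.44.

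Across the genome, 991 of 12123 tested genes changed, 585 higher and 406 lower in the GFP-RhoGDI2 line, and 201 of them by at least 2-fold, 158 higher and 43 lower. The genes with the largest measured rise after ARHGDIB were MAN1A1, a mannosidase of N-glycan trimming (log2 difference 4.87), RNF182 (4.12), DNER (4.10), the glutamate transporter gene SLC1A1 (4.07), the neurofilament gene NEFL (4.07), GRAMD2B (3.94), the actin-binding LIM protein gene ABLIM1 (3.89), TRIM6 (3.87), STC1, which encodes the secreted glycoprotein stanniocalcin-1 (3.72), CXCL1 (3.58) and TENM2 (3.45). Those with the largest measured fall were SPANXB1, a sperm-associated antigen (-3.98), VCAN (-3.11), the receptor phosphatase gene PTPRD (-2.90), HAPLN1, which links hyaluronan to proteoglycans (-2.52), the protocadherin gene PCDH19 (-2.28), ESM1 (-2.00), ZNF804A (-1.76), the carbonic anhydrase gene CA2 (-1.73), GULP1 (-1.69), PLEKHA5 (-1.64), the receptor tyrosine kinase gene KIT (-1.62) and the desmosomal gene DSP (-1.60). Their SEs ran from 0.092 for STC1 to 0.197 for PCDH19. The smallest of these SEs come mainly from the prior variance pooled over probe sets, and not from the measured spread of those genes. All 991 genes had the same sign in both pairs, which a call in this fit requires, so it is no separate evidence. The GFP means of MAN1A1, SLC1A1, NEFL, GRAMD2B, ABLIM1 and TRIM6, and of TNC and PPARG below, and the GFP-RhoGDI2 means of SPANXB1, VCAN and PCDH19, and of PKP2 and GPC4 below, lie under the filter level of 4.637; with no detection calls these are not shown to be above background, so the sizes and the order of these differences are uncertain. SLC1A1, NEFL, STC1, PTPRD and PLEKHA5, and among the list members named here LOXL2, PKP2, LTBP2, VLDLR, CRELD2 and POLR2A, lie in windows of 50 neighbouring genes whose median shifted beyond that of shuffled gene orders, as does the endogenous ARHGDIB. PTPRD moved against its window, whose median was 0.20 (KANK1 to SMIM27). The window from ARHGDIB to KIF21A had a median of -0.24. ARHGDIB was itself introduced, so its rise is no measure of the endogenous gene against that window. Over probe sets, 2085 of 27307 changed, 1264 higher and 821 lower.

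Without the preparation block, 641 genes were called, all among the 991, and 190 of the 201 genes with at least 2-fold change were among them. Leaving out 1 array without the block gave 400 genes without GFP A (268 higher, 132 lower), 421 without GFP B (302 and 119), 264 without GFP-RhoGDI2 A (204 higher, 60 lower) and 215 without GFP-RhoGDI2 B (152 and 63). The excess of higher calls was not kept above the upper quartile of mean values, with 902 higher and 974 lower, or with an intensity trend, with 1405 and 1474. Between preparations B and A, limma called 0 genes at adjusted p under 0.05 and 1217 had an unadjusted p under 0.05; with an intensity trend it called 190.

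**Figure D2:**
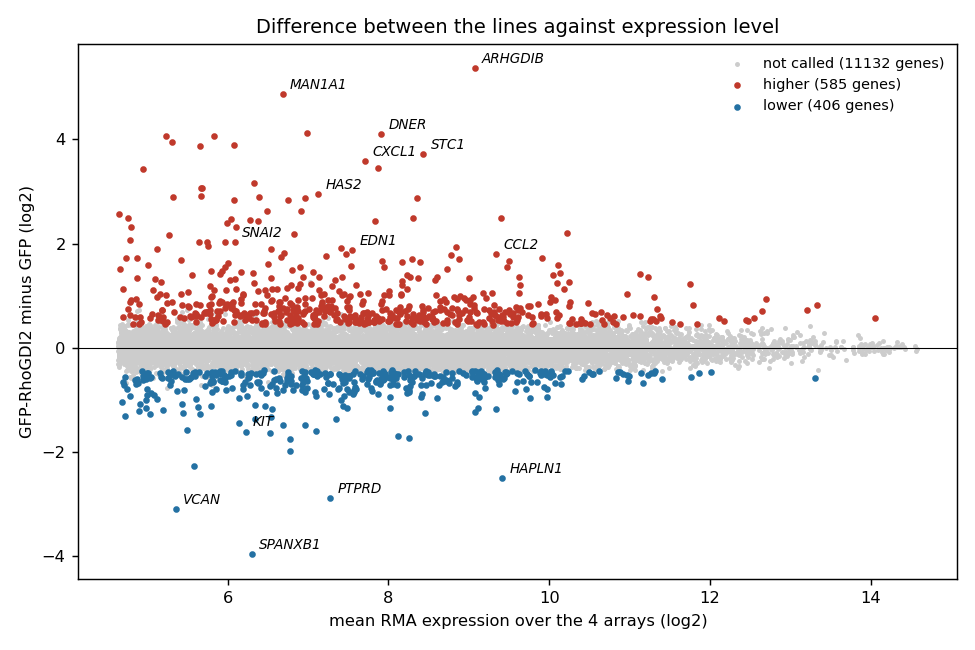
Log2 difference, GFP-RhoGDI2 minus GFP (vertical axis), against the mean log2 expression over the 4 arrays (horizontal axis), a point per tested gene. Red points are the 585 genes called higher, blue points the 406 called lower and grey points the 11132 not called; ARHGDIB lies at 5.37 and SPANXB1 at -3.98.

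Of 19 measured genes of cholesterol synthesis, 10 rose and 0 fell in the GFP-RhoGDI2 line (15 and 0 adjusted over the list alone), with a median log2 difference of 0.47. DHCR7, which catalyses the last step of the pathway, rose by 0.93, the sterol demethylation gene MSMO1 by 0.84, the sterol sensor gene INSIG1 by 0.81 and the lanosterol synthase gene LSS by 0.78. The list was past the set test (camera, adjusted p = 4.41e-08; adjusted p = 0.742 with an estimated correlation). Of the 11 lists past this test, 0 passed with an estimated correlation and 0 with fry, where the lowest adjusted p was 0.0785 and that of cholesterol synthesis 0.213. Estimated correlations in the 11 lists ran from -0.0769 (epithelial junction and keratin) to 0.5 (cancer-testis antigens), with 0.298 for cholesterol synthesis. These estimates rest on 1 residual degree of freedom. Where the true correlation exceeds the preset 0.01, the camera p-values are too small.

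Of 25 genes of angiogenesis and the hypoxia response, 11 rose and 0 fell (14 and 1 adjusted over the list alone), with a median of 0.41. The lymphatic growth factor gene VEGFC rose 3.38-fold, from 6.34 ± 0.02 to 8.10 ± 0.04 (SD, n = 2). DDIT4, an inhibitor of mTOR signalling induced by low oxygen, rose 3.30-fold, the carbonic anhydrase gene CA12 2.70-fold and NDRG1 2.08-fold. With camera the set test gave an adjusted p of 7.74e-08 (adjusted p = 0.742 with an estimated correlation).

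Chemokines and cytokines rose in 7 of 17 measured genes and fell in 0, with the same counts adjusted over the list alone. The neutrophil-attracting chemokine genes CXCL1, CXCL8 and CXCL3 rose 11.97-fold, 7.36-fold and 5.54-fold, and CCL2 rose 3.46-fold. CXCL8 went from 6.91 ± 0.35 to 9.79 ± 0.56 (SD, n = 2; adjusted p = 2.92e-04). The list median was 0.16 (0.198 in pair A, 0.0931 in pair B and 0.244 without the GFP B array and the block). For this list the set test gave an adjusted p of 9.62e-04 (adjusted p = 0.742 with an estimated correlation). Markers of macrophages and of lymphoid and blood cells did not move with these genes: 2 and 5 were measured above the filter, with medians of -0.13 and 0.03, and 0 were called in the main fit, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05.

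Mesenchymal markers rose in 5 of 15 measured genes and fell in 0 (6 and 0 adjusted over the list alone), with a median of 0.22 (0.338 without the GFP-RhoGDI2 A array and the block). SNAI2, a transcription factor that represses epithelial genes, rose from 5.07 ± 0.01 to 7.10 ± 0.38 (SD, n = 2), 4.08-fold. LOXL2, a collagen crosslinking enzyme, rose 2.99-fold and the transcription factor gene TCF4 2.91-fold. COL5A1 rose 1.69-fold with the block, a call that was lost without it (adjusted p = 0.0705). Its log2 difference was 0.76, and 0.49 without the GFP A array and the block. By camera, the list had an adjusted p of 6.70e-04 (adjusted p = 0.742 with an estimated correlation).

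Epithelial junction and keratin genes fell in 5 of 13 measured genes and rose in 1 (6 and 1 adjusted over the list alone), with a median of -0.17, which was -0.298 in pair A, -0.400 in pair B and -0.359 without the GFP-RhoGDI2 A array and the block. The desmosomal genes DSP and PKP2 fell by 1.60 and 0.87, and the keratin gene KRT8 fell by 1.23. The tight junction gene CLDN1 rose by 1.01, a call that was lost without the block (adjusted p = 0.0576). Camera gave this list an adjusted p of 0.0105 (adjusted p = 0.742 with an estimated correlation), and the call was lost without probe sets of the shared-transcript classes (adjusted p = 0.431).

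Genes of proteoglycans and hyaluronan moved both ways, with 4 of 19 higher and 3 lower (6 and 4 adjusted over the list alone). HAS2, a hyaluronan synthase, rose from 5.66 ± 0.22 to 8.60 ± 0.11 (SD, n = 2), 7.70-fold, while HAPLN1 fell 5.72-fold, and VCAN and the glypican gene GPC4 fell too. The median was 0.01, the mean -0.10 and the set test pointed upward with an adjusted p of 0.753, so these differ in sign and the list did not pass.

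Collagens and matrix glycoproteins rose in 6 of 20 genes and fell in 1, also when adjusted over the list alone, with a median of 0.23. The median was 0.377 without the GFP-RhoGDI2 A array and the block, and 0.130 with no filter on low values. LOXL2 rose 2.99-fold, the matrix glycoprotein gene TNC 2.48-fold, COL6A2 2.01-fold and TGFBI 1.95-fold, and COL12A1 was the gene that fell (-0.58). The called genes LOXL2 and COL5A1 count here and among the mesenchymal markers, so the results of these lists are not independent. For these genes camera gave an adjusted p of 0.0168 (adjusted p = 0.742 with an estimated correlation). The list's call and that of COL6A2 were lost without probe sets of the shared-transcript classes (adjusted p = 0.321 and 0.388), and the list's call was lost without the GFP-RhoGDI2 B array, where the median was 0.0708 (adjusted p = 0.113), and above the upper quartile of mean values, where the median was -0.0056 (adjusted p = 0.430); the median was 0.0624 in pair A and 0.298 in pair B.

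Matrix proteases and their inhibitors rose in 4 of 19 genes and fell in 1 (5 and 2 adjusted over the list alone). The metalloprotease genes ADAM12 and MMP2 rose 5.42-fold and 3.04-fold and the cathepsin gene CTSB 2.57-fold. The protease inhibitor gene SERPINE2 fell by 1.26. MMP1 differed by 1.26 with an SE of 0.316 and missed the threshold (adjusted p = 0.0712); its difference was 0.54 in pair A and 1.99 in pair B, and without the GFP-RhoGDI2 A array and the block it was 2.43 and called (adjusted p = 0.0247), as it was at 1.26 with an intensity trend (1.17e-04) and with the probe set mean (0.00273). The list median was 0.20, and the set test gave an adjusted p of 0.037 (adjusted p = 0.797 with an estimated correlation). The call was lost without the GFP A array (adjusted p = 0.118), without the GFP-RhoGDI2 B array (0.399), where the median was 0.0197, on ranks (0.110) and above the upper quartile of mean values (0.0639), where it was 0.0762; the median was 0.0497 in pair A and 0.229 in pair B.

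Integrin and focal adhesion genes rose in 3 of 22 cases and fell in 1 (5 and 2 adjusted over the list alone), with a median of 0.20. The median was 0.0708 in pair A, 0.273 in pair B and 0.175 without shared-transcript probe sets. ITGA4, CAV1 and CAV2 rose by 0.87, 0.82 and 0.62, the last pair encoding caveolins, and the collagen receptor gene ITGA2 fell by 0.81. The camera set test gave this list an adjusted p of 0.0240 (adjusted p = 0.742 with an estimated correlation). The call was lost without the GFP B array (median 0.127, adjusted p = 0.133), without the GFP-RhoGDI2 B array (median 0.114, adjusted p = 0.113) and without shared-transcript probe sets (0.182).

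TGF-beta and BMP genes rose in 4 of 23 cases and fell in 1 (5 and 1 adjusted over the list alone), with a median of 0.0525 (0.0863 without the GFP A array and 0.0841 without the GFP-RhoGDI2 A array, both without the block). The median was 0.0732 in pair A and 0.136 in pair B. The activin subunit gene INHBB rose 3.71-fold, LTBP1, whose product binds latent TGF-beta, 3.54-fold, the inhibitory SMAD6 2.33-fold and ID2 1.98-fold. LTBP2 fell by 0.60. With camera the set test gave an adjusted p of 0.0475 (adjusted p = 0.742 with an estimated correlation). That call was lost without the GFP-RhoGDI2 B array (adjusted p = 0.113), on ranks (0.105), above the upper quartile of mean values (0.345) and without shared-transcript probe sets, where the median was -0.0098 (adjusted p = 0.925).

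Cancer-testis antigen genes, which are normally expressed in the germ line, fell in 3 of 8 cases and rose in 0 (6 and 0 adjusted over the list alone), with a median of -0.46. MAGEC2, MAGEA4 and MAGEA10 fell by 0.96, 0.62 and 0.57, and MAGEA1 differed by -0.49 (adjusted p = 0.0658), called with an intensity trend (0.0302), with the probe set mean (0.00438) and, at -0.68, without the GFP A array and the block (0.0489). By camera, the list had an adjusted p of 0.00155 (adjusted p = 0.742 with an estimated correlation). Members of this family are near-identical and can share probes. The list's camera call was lost without probe sets of the shared-transcript classes (adjusted p = 0.182), where the median was still -0.31. With no filter on low values the list median was -0.053.

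**Figure D3:**
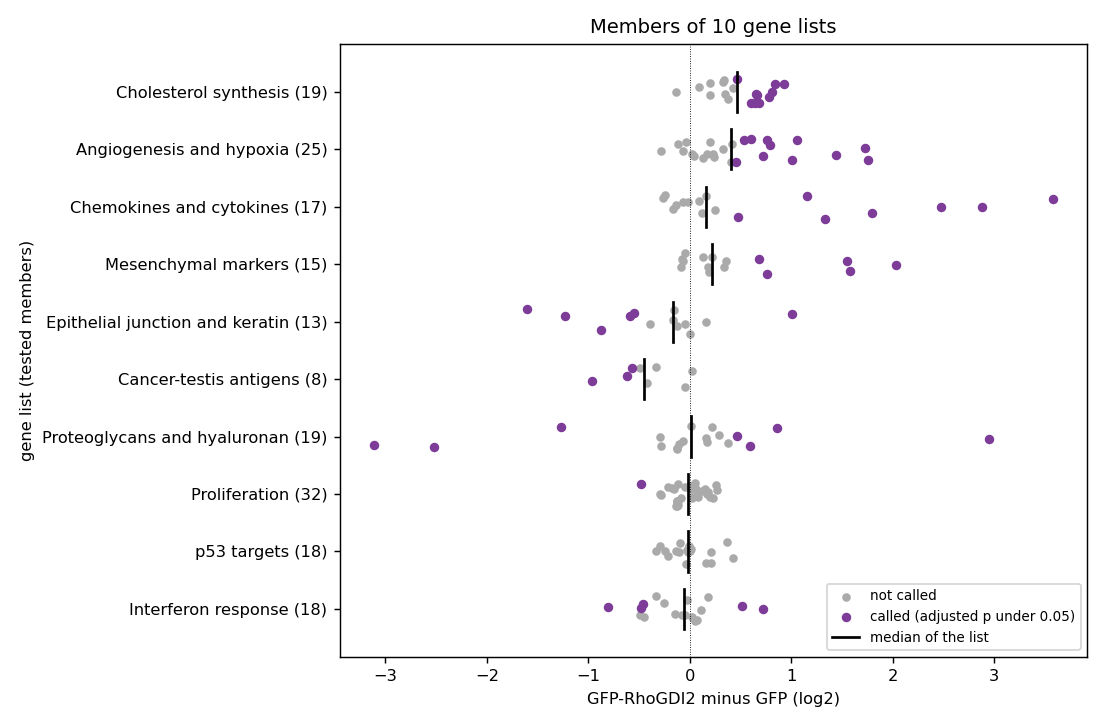
Log2 difference, GFP-RhoGDI2 minus GFP (horizontal axis), of the tested members of 10 gene lists (vertical axis, number tested in brackets), a point per gene. Purple points are called, grey points are not, and black bars are list medians; the median of cholesterol synthesis lies at 0.47 and that of cancer-testis antigens at -0.46.

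Targets of SRF and MRTF, transcription factors that respond to actin, had a median of 0.19 over 21 genes, with TPM2 alone called (0.58). Adjusted over the list alone, 2 were higher, and FHL2 differed by 0.43 (adjusted p = 0.0516). FHL2 and VCL (0.43 in the main fit) were called with an intensity trend (adjusted p = 5.09e-06 and 1.52e-04), above the upper quartile of mean values (0.00834 and 0.0172) and with the probe set mean (0.00352 and 0.0067). For FHL2 the probe set mean gave the same difference, so no further probe set adds to that call. Camera gave this list an adjusted p of 0.0168 (adjusted p = 0.742 with an estimated correlation). Without probe sets of the shared-transcript classes the list's call was lost (adjusted p = 0.478), as it was without the GFP-RhoGDI2 B array (0.103). With those probe sets left out, TPM2 was at -0.09 (adjusted p = 0.712) from another probe set, and with the probe set mean it was at 0.05 (adjusted p = 0.721).

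The other lists reported here did not pass the set test. Among 18 interferon-response genes, IRF9 and SAMD9 rose by 0.72 and 0.51 with the block, calls that were lost without it (adjusted p = 0.0604 and 0.0889), and IFI44, DDX60 and HERC6 fell by 0.81, 0.49 and 0.46; adjusted over the list alone, 2 were higher and 5 lower, and the set test gave 0.344. Of 32 proliferation genes, CENPE fell by 0.48, a call lost without the block (adjusted p = 0.236), and adjusted over the list alone 0 were called (set test 0.757). With 1 array left out and no block, CENPE lay between -0.199 and -0.766. In limma fits with an intensity trend, MKI67 and CDC6 were called lower (adjusted p = 0.00517 and 0.0216) and KIF20A higher (0.0177). MKI67 and CDC6 were also called lower above the upper quartile of mean values (0.0391 and 0.0324). Of 18 p53 targets, 0 were called in the main fit, also when adjusted over the list alone, and 4 had an unadjusted p under 0.05 (set test 0.935). CDKN1A was at 0.36 (adjusted p = 0.0783) and was called with an intensity trend (0.00311), above the upper quartile of mean values (0.0161) and with the probe set mean (0.00966), as were DDB2 (0.42 in the main fit), BAX (-0.34) and TIGAR (-0.29). With the probe set mean, CDKN1A, DDB2 and TIGAR kept the same differences, so no further probe set adds to those calls. Of 26 genes of the unfolded protein and amino acid response, VLDLR, CRELD2 and PSAT1 rose by 1.04, 0.62 and 0.61, PSAT1 only with the block (adjusted p = 0.103 without it); adjusted over the list alone 4 were higher and 2 lower (set test 0.463). Of 7 urothelial markers, PPARG, a nuclear receptor of urothelial differentiation, rose by 1.27 (set test 0.259), and of 10 endothelin and neuropeptide genes EDN1 rose (set test 0.757). Adjusted over the list alone, 1 urothelial marker was higher, and of the endothelin and neuropeptide genes 1 was higher and NMU lower. Of 12 housekeeping genes, YWHAZ rose by 0.52 and POLR2A fell by 0.49, the latter a call lost without the block (adjusted p = 0.0758), and adjusted over the list alone 2 were higher and 1 lower (set test 0.452). The 5 lymphoid and blood markers gave a set test of 0.935. The 2 fibroblast and endothelial markers measured, THY1 and PECAM1, differed by -0.14 and -0.07 and were not called, also when adjusted over the list alone.

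The 3' minus 5' log2 difference of the control probe sets, a measure of RNA integrity, differed between the groups by -0.14 for ACTB, more than the 0.082 between arrays of a group, and by -0.015 for GAPDH, within the 0.032 between arrays of a group.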

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

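Tests chosen only after the result was seen are those of the probe sets of VCAN and HAPLN1, of the agreement between pairs A and B and of the share of called genes with shifted neighbours; the others were written down beforehand.

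Probe sets outside the gene-level comparison also differed. Among tested probe sets that name no single gene, 246 were called, 131 higher and 115 lower in the GFP-RhoGDI2 line, 38 of them by at least 2-fold. With the level filter left off, 192 probe sets below it were called, 136 higher and 56 lower.

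Many genes differed between the lines. After each array was centred on its median, 95.16% of the called genes stayed called, and the median log2 difference of all tested genes was -0.013. The deposited arrays already had nearly equal medians, so centring could change little and this cannot decide on the scaling of the arrays. For RNA quality as the cause, both controls were to differ between the groups in the same direction, beyond the spread between arrays. The GAPDH 3' minus 5' difference between the groups was -0.015, within that spread, but that of ACTB was -0.14 and beyond it. The controls disagree, so they cannot decide on RNA quality. Copy number differences as the source of most calls would need the 10 neighbours on each side of a called gene to shift with it by at least 0.2; the median shift was 0.0438 (95% interval 0.0348 to 0.0511), well below that value but above the highest of 200 shuffled gene orders (0.0046), and its interval crosses the 0.05 set in advance for setting this explanation aside. For a part of the called genes, 13.55%, the neighbours did shift by at least 0.2 the same way, against at most 0.61% in shuffled orders, which neighbours regulated together would also give, so copy number may contribute and cannot be told apart from shared regulation without DNA measurements. Differences between the transfected lines other than RhoGDI2 also stay open and cannot be told apart from its effect: the log2 differences of pairs A and B correlated at r = 0.9734 across the called genes (not independent, and chosen as called), as both would give, and the effect of RhoGDI2 itself was not tested separately.

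CXCL8, CXCL1, CCL2 and EDN1 were higher in the GFP-RhoGDI2 line. Macrophages or blood cells among these cells, which the sort for fluorescence would largely remove, would bring their own transcripts; the tested markers had a median log2 difference of -0.0813 with 0 of 7 called, and without the filter LYZ, TYROBP, FCER1G, LAPTM5, CD53 and PTPRC lay between -0.11 and 0.23. An interferon response to introduced DNA that was stronger in the GFP-RhoGDI2 line would raise the interferon list, whose median was -0.0626. Both lines had been transfected, so a response shared by both would cancel in this difference and could not be seen. Regulation downstream of RhoGDI2 and differences between the lines both stay open and may account for the pattern.

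VCAN and HAPLN1 were lower in the GFP-RhoGDI2 line. Each of the 6 tested probe sets of these genes was lower by at least 2.5, the smallest fall being a log2 difference of -2.5161. None of the 6 thus stayed unchanged or went the other way. The filter used the mean over both lines, so a probe set low in the GFP-RhoGDI2 line passed only through a high GFP level. These values therefore cannot decide on a probe set effect. Probe sets under the filter, where one low in both lines could show no change, were not counted. A lower level of matrix genes in general is argued against by the collagens and matrix glycoproteins, whose median was 0.2257, although it fell to 0.0708 without the GFP-RhoGDI2 B array and to -0.0056 above the upper quartile of mean values, and not to the -0.3 of such a fall. An effect of RhoGDI2 on these genes and a difference between the lines both stay open and may account for the pattern.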

How the results depend on the processing

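The list test with an estimated correlation and no replicate block and the removal of genes in shifted windows were chosen after seeing the data. The 991 called genes became 641 with no replicate block (1284 probe sets against 2085), 215 to 421 genes and 422 to 909 probe sets without the block and with 1 array left out (fewer arrays), 1876 and 3435 in the set above the upper quartile of mean values, 2879 and 5721 with an intensity trend, 2314 genes with the mean of a gene's probe sets, 1971 and 4264 at adjusted p under 0.10, 201 and 379 with a 2-fold minimum, 163 and 293 with the fold rule in both pairs, and 0 and 0 with the plain paired test on 1 degree of freedom (1540 genes at unadjusted p under 0.05). Higher against lower calls were 902 and 974 above the upper quartile, 1405 and 1474 with the trend and 1198 and 1116 with the probe set mean, against 585 and 406. Total counts stayed within 1.5 times elsewhere: 695 genes with no filter, 969 robust, 871 after quantile normalization, 1013 centred, 994 with a floor, 789 without shared-transcript probe sets and 752 without the shifted windows; of these totals, the lower calls were 235 with no filter and 263 without the windows, against 406, both beyond 1.5 times. Preparations differed in 190 genes with the trend, 89 with the probe set mean and 0 elsewhere. With the probe set mean, NMU, MMP1, MAGEA1, FHL2, CDKN1A, DDB2 and TIGAR kept the differences of the main fit. Their calls there came from the pooled variance and the adjustment over genes, and not from further probe sets. Of the 11 lists past the threshold, 0 held with an estimated correlation, with the block or without it, and 0 with fry (lowest adjusted p 0.0785), 5 without shared-transcript probe sets, 8 above the upper quartile, 9 on ranks, 10 without the shifted windows (collagens, adjusted p = 0.0523) and 6 to 11 with 1 array left out, 6 without GFP-RhoGDI2 B. With the block, the estimated-correlation test had 1 residual degree of freedom, so its 0 lists say little about correlation between genes. Cholesterol synthesis, hypoxia, chemokines and mesenchymal markers held everywhere except with an estimated correlation and fry. No list gained or lost its call when only the block was dropped. Urothelial markers passed with the probe set mean (adjusted p = 0.0415) and the unfolded protein response without GFP-RhoGDI2 B (0.0174), where 7 lists passed in all. List medians moved by over 1.5 times also where the call held: chemokines from 0.16 to between 0.0855 (no filter) and 0.474 (above the upper quartile), epithelial genes from -0.17 to between -0.0732 and -0.472 in the same settings, and mesenchymal markers from 0.22 to 0.353 without shared-transcript probe sets. TPM2 reversed to -0.0896 without shared-transcript probe sets. Of 77 called genes the text's rule names, 48 kept their call in every limma fit that measured them, at adjusted p under 0.05; with 1 array left out and no block, 18 to 28 lost it. ARHGDIB stayed called in each limma fit that measured it, at 2.10 with the probe set mean. The cause of these shifts was not tested beyond the smaller number of arrays or genes. Leaving out a pair leaves no residual degrees of freedom: genes at least 2-fold different in the mean then numbered 201 to 231, against 202. For a random block, duplicateCorrelation in limma gave an estimate for 0 of 27307 probe sets with these 4 arrays, so that alternative was not run; no other tool was tried. Signal near the low end limits what can be called there. Simulated changes of 0.5 were recovered in 8% of cases, with far fewer probe sets changed than were called in the data.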

Other observations

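All groups of genes and tests in this part were chosen after the values were seen.

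These are single called genes outside the lists, from which nothing follows for a group. MYLK, encoding myosin light chain kinase, rose 7.31-fold, from 5.53 ± 0.32 to 8.40 ± 0.38 (SD, n = 2). EPS8, an actin-capping signalling adaptor, rose 7.10-fold, the tensin gene TNS3 6.20-fold, MARCKS 4.61-fold and KANK1 2.57-fold. The prostaglandin E2 receptor gene PTGER4 and the bradykinin receptor gene BDKRB1 rose by 2.90 and 2.49, P2RY1 and ADRB1 fell by 1.27 and 1.32, RGS4 rose by 3.07 and RGS2 fell by 1.19. VCAM1, RUNX2, GJA1 and WNT5A rose by 2.48, 2.56, 2.50 and 1.94, and the Wnt inhibitor gene DKK1 fell by 1.16. All of these had an adjusted p under 0.05, which in this fit also requires the same sign in both pairs. EPS8, KANK1 and BDKRB1 lie in windows of neighbouring genes that shifted together (below). EPS8 and BDKRB1 rose against their windows, whose medians were -0.24 (ARHGDIB to KIF21A) and -0.22 (TDP1 to CCDC85C). The GFP means of RGS4, VCAM1 and RUNX2 and the GFP-RhoGDI2 means of ADRB1 and RGS2 lie under the filter level and are not shown to be above background, so the sizes of these differences are uncertain.

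Of 348 tested zinc finger genes with ZNF symbols, 8 were called higher and 29 lower, against 577 and 377 among other genes. Their median log2 difference was -0.11. The group was picked because its fall had been seen, so no test on these arrays is independent evidence of it. The set test with an estimated correlation, on 1 residual degree of freedom, gave p = 0.0847. Without the block, 3 were higher and 18 lower.

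Neighbouring genes shifted together in places. Of 451 windows of 50 genes in chromosome order, 30 had a median log2 difference past the largest of 200 shuffled orders (0.177), 6 higher and 24 lower in the GFP-RhoGDI2 line; windows overlap, so they are not independent. The window from MGC70870 to PELP1 had a median of -0.31 with 14 genes called lower and 0 higher, and that from PLCXD1 to RPS6KA3 a median of 0.28 with 12 called higher and 0 lower. Each had the same sign in both pairs (-0.35 and -0.26, 0.28 and 0.28). The windows held 195 of the 989 called genes placed, 19.7%, and 1100 of the 12101 tested genes placed; 794 called genes lay outside. With their genes removed, 752 genes were called and 10 lists passed, so the regions may account for a part of the calls only; DNA copy number was not analysed here.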
